A study of Mus musculus with 4 samples.

How the data were processed

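RNA was measured from the atrioventricular canal (AVC) of mouse hearts at embryonic day 10.5. The AVC is the short segment between the embryonic atria and ventricles that forms the endocardial cushions and contributes to the atrioventricular conduction system. Per the labels' protocols, embryos were collected in ice-cold saline, the AVC was micro-dissected and frozen in lysis buffer, tissue pieces from 5 hearts were pooled for each sample, and total RNA was purified on columns and amplified linearly with the 2-colour low-input kit of Agilent. The design text names 2 conditions, wild type and Tbx3 hypomorphic mutant, with 4 biological replicates. Each of the 4 arrays carried 1 control pool labelled with Cy3 (green) and 1 mutant pool labelled with Cy5 (red). The labels give the same dye orientation for all 4 arrays, so a dye effect particular to a gene cannot be told apart from the genotype in these data. All 4 arrays lay on 1 slide and were read in 1 scan, per the file headers, so slide and scan date could not be tested as batches.

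The authors deposited the scanner output of Agilent Feature Extraction 9.5.1, per the file headers and the submitters' processing notes, for a 60-base oligonucleotide array with 45018 spots, of which 43379 were not controls. The deposited spot intensity is the mean pixel signal of each channel before background subtraction, with the median of the local background beside it. The deposited processed signals are a second kind of intensity, which the scanner software had background-subtracted, spatially detrended and dye-normalized, per the file headers. The deposited log10 ratio is red over green, so a positive value means a higher signal in the mutant pool. The deposited series table held the same log10 ratio for each array to within 5e-07, with column medians of 0, not centred per gene. Scale and direction of that table were settled by this match. Other deposited columns used were flags for spots well above background, saturated spots and non-uniform spots. Positions of probes are those the files give for mouse build mm7, and no annotation of that build was used here, so whether a probe lies in an exon or an untranslated region is not stated. No column of the files lacked a sample.

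From the intensity columns, background was corrected with normexp and an offset of 50, and each array was normalized within itself by loess with control spots at weight 0 (limma 3.58.1 in R 4.3.3). Non-uniform spots were left out, and spots of one probe were averaged. Of 41174 probes, 28794 were well above background in at least 1 channel on at least 3 of the 4 arrays and were kept. Where a gene had several probes, the probe with the highest mean log2 intensity (A) was taken, without reference to its ratio. Probe names were updated through the accessions, symbols and synonyms of a RefSeq gene table: 22951 probes were named by accession, 6659 by a current symbol and 3109 by a unique synonym, and 8455 kept the name in the files. This left 19091 genes. The log2 ratio of mutant over control was tested against 0 with lmFit and eBayes, 2-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05; a second count required an absolute log2 ratio of at least 1, and a looser count used an adjusted p under 0.1. Every adjusted p given without another name comes from this limma fit. Each array pairs 1 mutant pool with 1 control pool, so the ratio within an array is the unit of analysis and n = 4 throughout.

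Before the data were examined, 28 gene lists were written from textbook knowledge. They cover chamber myocardium, atrial and ventricular chambers, the AVC and node, sarcomere, ion channels, cushion mesenchyme, endocardium, epicardium, erythroid cells, leukocytes, second heart field, neural crest, liver and lung bud, 2 phases of the cell cycle, cell cycle inhibitors, the p53 response, hypoxia and glycolysis, immediate early genes with heat shock genes, T-box genes, 4 signalling groups, cardiac transcription factors, sex-linked genes and the chromosomal neighbours of Tbx3. Each list was compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Members past the threshold were counted over all genes tested and adjusted over the list alone. Camera with an estimated correlation, fry, and the lists without genes that lists share were alternatives. With an estimated correlation camera also takes its p from the 3 residual degrees of freedom of the arrays. A call lost there therefore need not be lost because of correlation.

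The rule for naming genes was fixed at the same time. It names Tbx3, then up to 12 genes per direction past the threshold with the same sign on all 4 arrays, then up to 4 members of each list past the threshold or, in a list with none, the 2 members with the highest A, and in every case a fixed set that includes Nppa, Gja5, Gja1, Tbx2, Bmp2, Hcn4 and Cacna1g. Since 1 gene passed, most named genes are given as values. Genes past the looser limit are named because that count was planned, and list members that passed only when adjusted over the list alone, or over all genes only without array 2, are named with that adjustment or setting. Other genes named were chosen after their values were seen, and the text says so.

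Between 67.0% and 68.4% of spots were well above background in the control channel and between 68.8% and 72.4% in the mutant channel. At most 2 spots per array were saturated in either channel. The number of arrays limits the precision, and 8 sign patterns of the 4 arrays are too few to give a share under 0.05. The tests were tested on simulated ratios for 19089 genes with the estimated prior variance and independent noise, 200 of them changed. Over 10 simulations, 24.8% of genes changed by 0.5 on the log2 scale were recovered, 83.0% of those changed by 1, and 98.0% of those changed by 2 or by 3. Of the calls, 5.55% were unchanged genes. Changing 200 genes makes the adjusted threshold easier to reach than in the real data, where 1 gene passed. These shares are therefore not the power of the real comparison. There Cacna1g, at -1.04 ± 0.19, had an adjusted p of 0.0948. A list of 30 genes shifted by 0.5 reached an unadjusted camera p under 0.05 in every one of 100 simulations, and an unchanged list in 2% of them. The list calls of the report are adjusted, and the genes of a list are not independent. The estimated correlation was 0.28 for hypoxia and glycolysis and also for sarcomere. The 2% is therefore not the error rate of those calls. Real arrays differed more from each other than these simulations assume, as the report gives.

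Alternatives fixed beforehand were the scanner software's processed signals, the series table, no background subtraction, median centring, Aquantile scaling after loess, removal of a trend with probe GC content, no filter on dim probes, a stricter filter, all probes separately, the mean over probes, a variance trend with robust estimation, array weights, a statistic without variance moderation, the 2 channels as separate samples without the array as a block, and each array left out in turn. A further pair was added after the data were seen: removal of each array's running median over the 50 probes next brighter and the 50 next dimmer, and the same without array 2. Camera with an estimated correlation and without array 2 was also added then.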

Results

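Transcripts of the embryonic mouse AVC were compared between wild type controls and mutants that carry a hypomorphic (reduced-function) Tbx3 genotype. Tbx3 encodes a T-box transcription repressor that is expressed in the AVC and the later conduction system. The comparison asks which genes depend on a normal dose of Tbx3 in the AVC at this stage. The data are 4 arrays, each giving the ratio of 1 mutant pool to 1 control pool of 5 hearts, so 8 pools entered in all. Median spot signals lay between 117.9 and 133.5 in the control channel and between 175.1 and 232.5 in the mutant channel, before normalization. Ratios are on the log2 scale, mutant over control, as mean ± SD over the 4 arrays unless another error is named.

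Tbx3 fell in the mutant AVC and was the only 1 of 19091 genes past the threshold. Its log2 ratio was -1.35 ± 0.10 (SD, n = 4; adjusted p = 0.0454), with -1.35, -1.40, -1.43 and -1.21 on arrays 1 to 4, so the transcript was lower on all 4. The probe lies on chromosome 5 from 118918450 to 118918509 in build mm7. A second, dim probe for Tbx3, from 118906718 to 118906777 on the same chromosome, was well above background on 3 control and 1 mutant channels and read -0.14 ± 0.12; the brighter probe stands for the gene. The labels do not give the structure of the hypomorphic allele, so whether either probe lies in an altered part of the gene is not known. Tbx3 was past the threshold in 11 of 20 alternative settings, with a negative ratio in all 20, and when array 1, 3 or 4 was left out its adjusted p lay between 0.346 and 0.602, with log2 ratios between -1.39 and -1.32. Averaged over all probes of the gene instead, the log2 ratio was -0.74 (adjusted p = 0.120).

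**Figure D1:**
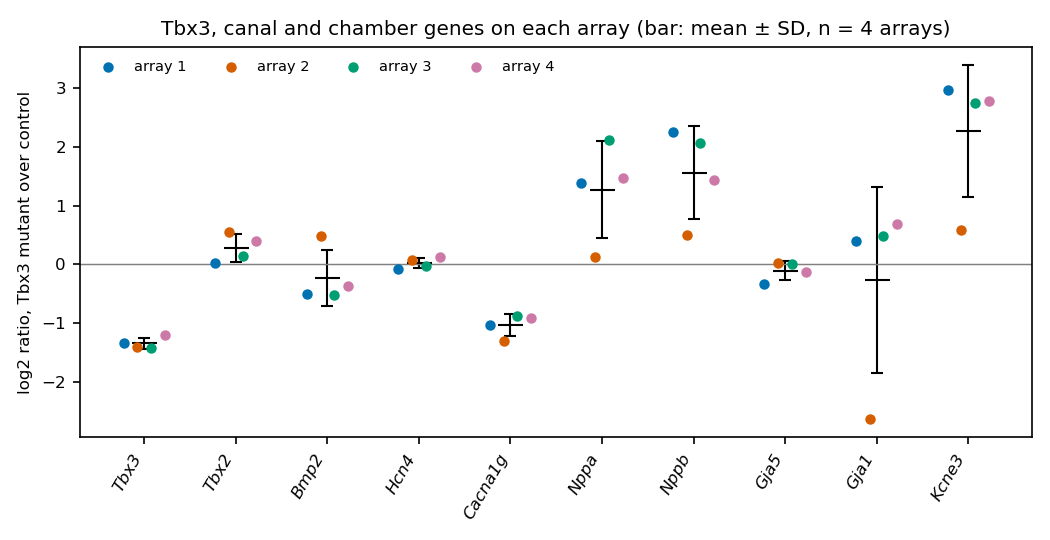
Log2 ratio of mutant over control (vertical axis) for Tbx3 and for AVC and chamber genes (horizontal axis) on arrays 1 to 4, as coloured points, with the mean and SD over the 4 arrays as a bar. Tbx3 lies between -1.43 and -1.21 on all arrays, whereas Gja1 lies at -2.64 on array 2 and between 0.39 and 0.68 on the others.

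With Tbx3 included, 26 transcripts had an adjusted p under 0.1, 13 higher and 13 lower, and the other 25 did not pass the main threshold. Those with lower values included Cacna1g, a T-type calcium channel of pacemaker and conduction cells, at -1.04 ± 0.19 (adjusted p = 0.0948; lower on 4 of 4 arrays), and the glucagon receptor gene Gcgr at -1.09 ± 0.23. Tceal6 and Tceal3, which belong to the transcription elongation factor A-like family, stood at -1.08 ± 0.19 and -0.74 ± 0.14. Gtsf1 at -0.91 ± 0.13, Strip2 at -0.83 ± 0.13, Cidea, a lipid droplet protein, at -0.77 ± 0.06, Map2, a neuronal microtubule protein, at -0.71 ± 0.09, Col9a3 at -0.68 ± 0.11 and Rab40b at -0.62 ± 0.09 were also on the lower side, as were the sequences BU562039 and AV152162. Those with higher values included 3 glycolytic enzymes, Pgk1 at 1.27 ± 0.31, Ldha at 1.17 ± 0.26 and Aldoa at 0.97 ± 0.23. The slow myosin heavy chain Myh7 stood at 1.09 ± 0.22 and the stretch-responsive muscle gene Ankrd1 at 1.05 ± 0.25. Rack1 and Rpl19 of the ribosome were at 0.78 ± 0.12 and 0.71 ± 0.14, Jmjd6 at 0.70 ± 0.09, the ATP synthase genes Atp5a1 and Atp5b at 0.65 ± 0.08 and 0.61 ± 0.05, the myosin light chain Myl6 at 0.62 ± 0.04 and Izumo4 at 0.61 ± 0.08. Adjusted p values of these genes lay between 0.0948 and 0.0991. Other probes past the filter did not rise for Izumo4 (-0.06 ± 0.20) or Atp5a1 (0.03 ± 0.13), and read 0.25 ± 0.27 and 0.0052 ± 0.09 for Atp5b, 0.35 ± 0.06 for Myl6, 0.26 ± 0.16 for Rack1, 0.21 ± 0.17 for Rpl19 and 0.17 ± 0.16 and 0.22 ± 0.12 for Jmjd6. Those of Pgk1, Myh7, Aldoa and Ldha read 1.13 ± 0.35, 1.07 ± 0.28, 0.69 ± 0.27 and 0.62 ± 0.28. On the lower side a second probe of Gtsf1 read -0.72 ± 0.14, and dimmer ones of Cacna1g, Rab40b and Strip2 read -0.34 ± 0.14, -0.23 ± 0.08, and -0.29 ± 0.06 and -0.13 ± 0.09.

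Of the 13 transcripts with higher values at the looser limit, 11 were measured by very bright probes with a mean A above 16, and none of the 13 with lower values was. After loess the 243 probes with A between 16 and 17 had medians between 0.19 and 0.32 on the 4 arrays, and the 88 probes above 17 had medians between 0.50 and 0.83. A list of 29 ribosomal protein genes, written after this trend was seen, had medians of 0.80, 0.35, 0.42 and 0.40 on arrays 1 to 4. With each array's running median removed, the median of the 13 higher transcripts went from 0.71 to 0.38 and that of the 13 lower ones from -0.81 to -0.79. All 26 kept their sign, and 1, Tbx3, was left at an adjusted p under 0.1. The other 12 lower transcripts then had adjusted p values between 0.130 and 0.179, and the 13 higher ones between 0.153 and 0.904.

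**Figure D2:**
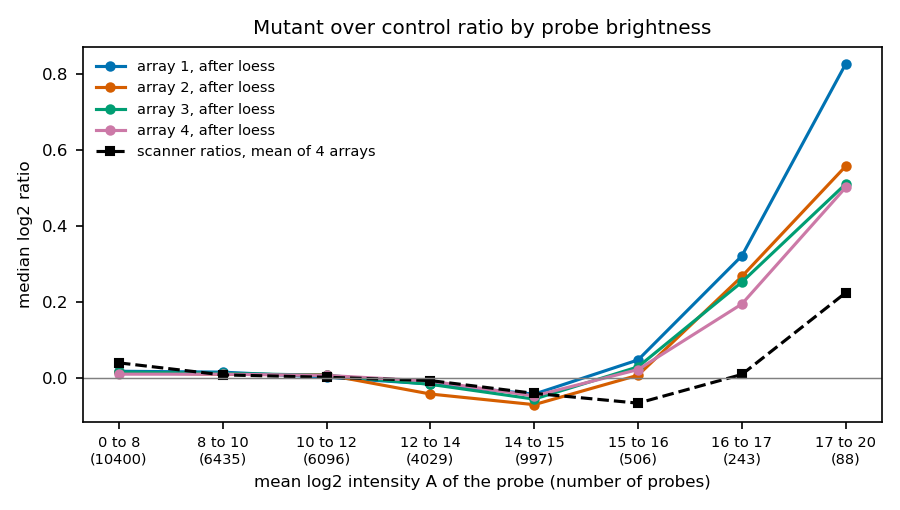
Median log2 ratio (vertical axis) of probes in 8 classes of mean log2 intensity A (horizontal axis, with the number of probes in each), for arrays 1 to 4 after loess and for the mean of the scanner software's own ratios. Medians stay near 0 up to A = 16 and reach 0.60 on average above 17 after loess, against 0.22 in the scanner software's ratios.

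Over all genes, 2778 had an unadjusted p under 0.05, against 954.6 for chance alone, and 24.9% had the same sign on all 4 arrays, against 12.5% for unrelated arrays. Dye effects particular to genes and shared by the 4 arrays would raise both values too. The excess therefore cannot be put down to genotype alone. The arrays differed from each other. Across 19089 genes, which are not independent replicates, Pearson's r was 0.66 between arrays 3 and 4, 0.35 between 1 and 4 and 0.25 between 1 and 3, but 0.07, -0.06 and -0.02 between array 2 and arrays 1, 3 and 4. The SD of the log2 ratios was 0.49 on array 2 and between 0.26 and 0.29 on the others. Without array 2, 193 genes passed the threshold, 130 higher and 63 lower, and without array 1, 3 or 4 none did, at 2182, 1497 and 1534 genes with an unadjusted p under 0.05. Leaving out array 2 gave 4436 of 19091 genes at an unadjusted p under 0.05, against 2778 on 4 arrays. Small p values were thus more frequent among all genes in that setting. Counts over a list alone without array 2, given later, are not shown to be particular to a list.

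Genes of hypoxia and glycolysis stood higher in the mutant AVC as a group. All 30 measured members of the list had a positive mean, 26 were higher on all 4 arrays, and the list's median was 0.62 (medians on arrays 1 to 4 were 0.77, 0.37, 0.72 and 0.54). The members included the glucose transporters Slc2a1 at 0.75 ± 0.21 and Slc2a3 at 0.89 ± 0.33, the angiogenic factor Vegfa at 0.78 ± 0.33, the mitophagy gene Bnip3 at 0.93 ± 0.29 and Egln3, an oxygen-sensing prolyl hydroxylase, at 1.36 ± 0.94. None passed over all genes, but 22 passed when adjusted over the list alone, all of them higher, with Ldha, Pgk1 and Aldoa at 0.00135. Camera with its preset correlation gave an adjusted p of 5.92e-22 over the 28 lists. That call was lost with an estimated correlation (adjusted p = 0.492), and fry, which asks whether a list moves one way on balance, gave an adjusted p of 0.0540. Without array 2 the median was 0.69 (adjusted p = 0.853 with an estimated correlation). Of the members 12 then passed over all genes and 26 over the list alone, all higher. With the preset correlation, other sign patterns of the 4 arrays called between 2 and 7 of the 28 lists, against 6 for the real pattern.

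**Figure D3:**
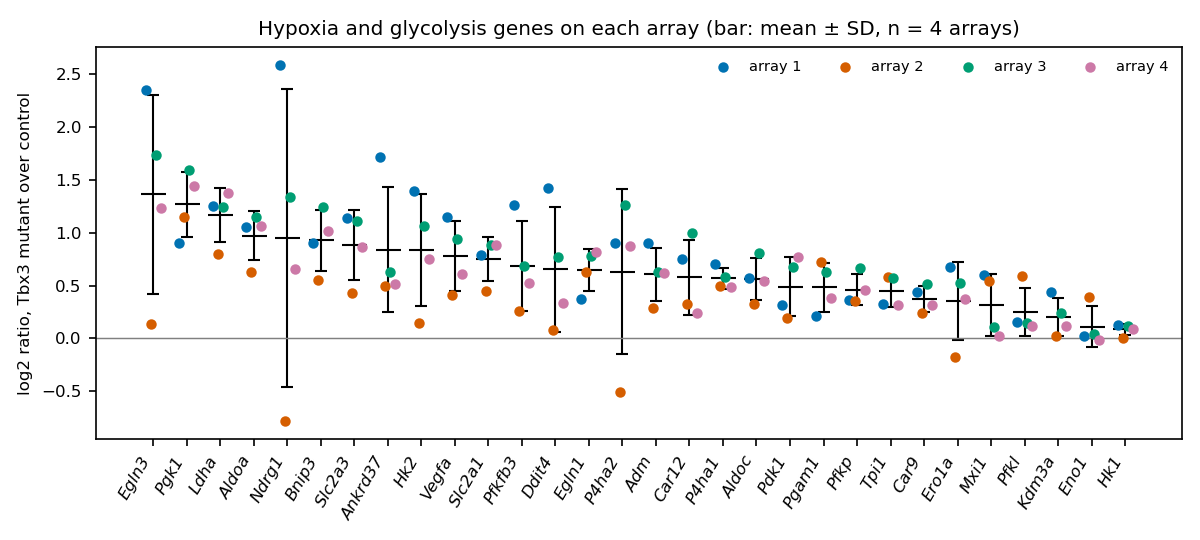
Log2 ratio of mutant over control (vertical axis) for the 30 measured genes of the hypoxia and glycolysis list (horizontal axis) on arrays 1 to 4, with the mean and SD over the 4 arrays as a bar. All 30 means are positive, and 26 genes lie above 0 on every array.

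Markers of working chamber muscle stood higher in part, and the natriuretic peptide genes had the highest means in their list. Nppa, atrial natriuretic peptide and a marker of chamber as opposed to canal muscle, was at 1.28 ± 0.83 (adjusted p = 0.201), with 0.13 on array 2 and between 1.38 and 2.12 on the others. Nppb and the homeobox gene Irx1, named after their values were seen, were at 1.57 ± 0.79 and 0.96 ± 0.61. Some other chamber genes had negative means: the gap junction gene Gja5 was at -0.11 ± 0.16 and the LIM protein gene Fhl2, one of the 2 brightest members, at -0.33 ± 0.22. Gja1, at -0.27 ± 1.58, was at -2.64 on array 2 and between 0.39 and 0.68 on the others, with a mean of 0.52 without array 2 (adjusted p = 0.0609). Of 23 measured members 16 had a positive mean, the median was 0.16, no member passed over all genes or adjusted over the list alone, and camera gave an adjusted p of 0.0262 (adjusted p = 0.866 with an estimated correlation). Without array 3 this call was lost (adjusted p = 0.0741), and without array 2 Nppa, Nppb, Irx5 and Irx6 passed over all genes and 9 members over the list alone, 8 higher and 1 lower.

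Sarcomere genes also stood higher, and so did the ventricular list, which shares members with them. Of 32 sarcomere genes 25 had a positive mean and 15 passed when adjusted over the list alone, 14 higher and 1, the intermediate filament gene Des, lower at -0.22 ± 0.09. Besides Myh7, the myosin light chains Myl7, Myl3 and Myl4 were at 1.04 ± 0.29, 0.77 ± 0.20 and 0.74 ± 0.16, and the troponin gene Tnnt2 at 0.60 ± 0.17. The median was 0.24 (camera adjusted p = 6.26e-07; adjusted p = 0.866 with an estimated correlation). Of the 10 sarcomere genes with a mean above 0.5, 8 had an A above 16, and the median was 0.12 with the running median removed (adjusted p = 0.0260), which fell to 0.05 without array 2 as well (adjusted p = 0.412). With array 2 left out but the running median kept, it was 0.21 (camera adjusted p = 0.00057). Myh7, Myl3, Myl4 and Myl7 then passed over all genes, and over the list alone 15 members passed, 13 higher and 2 lower. The ventricular list had a median of 0.12 over 15 genes (camera adjusted p = 0.0262; adjusted p = 0.851 with an estimated correlation). Its 4 members past the threshold adjusted over the list alone, all higher, were Myh7 and Myl3, which are also in the sarcomere list, Mycn at 0.44 ± 0.13 and Nrg1 at 0.30 ± 0.11, and the list's call was lost without array 2 (adjusted p = 0.236). In that setting 10 members passed over the list alone, 7 higher and 3 lower. Without the genes that lists share, fewer than 5 ventricular members were left and the list was not tested. In the atrial list, with a median of 0.11 over 16 genes (camera adjusted p = 0.214), Myl4, Myl7, Dkk3, Nppa and Bmp10 passed when adjusted over the list alone, all higher. Without array 2 this list's median was -0.00297 (camera adjusted p = 0.732), and 9 members passed over the list alone, 5 higher and 4 lower.

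Genes of the AVC and node itself were spread around 0 apart from a few. Of 29 genes, 4 passed when adjusted over the list alone, all lower: Tbx3, Cacna1g, the Wnt agonist gene Rspo3 at -0.66 ± 0.37 and Cpne5 at -0.45 ± 0.23. Tbx2, the T-box gene closest to Tbx3, was at 0.28 ± 0.24, its activator Bmp2 at -0.23 ± 0.48 and the pacemaker channel Hcn4 at 0.02 ± 0.09, none past the threshold. The median was -0.05 (camera adjusted p = 0.213), with 0.30 on array 2 and -0.29, -0.26 and -0.02 on arrays 1, 3 and 4. Without array 2 the median was -0.23 (camera adjusted p = 0.000437; adjusted p = 0.853 with an estimated correlation) and Tbx3, Cacna1g, Msx2, Slitrk5 and Cpne5 passed over all genes, all lower. Over the list alone 12 then passed, 1 higher and 11 lower. Of the 10 T-box genes measured Tbx3 alone passed, over all genes and adjusted over the list alone, and the list's median was -0.000187 (camera adjusted p = 0.690). Fry in its directional form gave this list an adjusted p of 0.0338. With array 2 left out, 2 T-box members passed over the list alone, both lower.

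Among 49 genes of ion channels and calcium handling, Kcne3, a potassium channel subunit, had the largest mean, 2.27 ± 1.13, with 0.59 on array 2 and between 2.76 and 2.97 on the others. Kcne3 passed when adjusted over the list alone, as did Cacna1g and the sodium channel subunit Scn2b at -0.44 ± 0.15. The calcium pump gene Atp2a2, a bright member that had no call, was at 0.47 ± 0.34. The median was 0.02 (camera adjusted p = 0.806). Without array 2 it was 0.0045 (camera adjusted p = 0.728). Over the list alone 14 members then passed, 6 higher and 8 lower, and Kcne3, Cacna1g and the potassium channel Kcnj12, at -0.52, passed over all genes.

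Cushion mesenchyme genes stood lower as a group. Of 40 measured genes 9 had a positive mean, the median was -0.21, and camera gave an adjusted p of 0.00222 (adjusted p = 0.492 with an estimated correlation). The estimated correlation of this list was 0.0102, close to the preset 0.01, so correlation does not account for that loss. Sfrp2, a secreted Wnt modulator, was at -0.76 ± 0.21 and was the 1 member that passed when adjusted over the list alone. Postn, a matrix protein of the cushions, and the homeobox gene Prrx1, named after their values were seen, were at -0.94 ± 0.60 and -0.55 ± 0.24 and were lower on all 4 arrays. The brightest members, Vim and Mdk, were at 0.27 ± 0.15 and -0.07 ± 0.18. On array 2 the collagen genes Col1a1, Col1a2 and Col3a1, named after their values were seen, had ratios of -3.58, -2.58 and -2.37, against values between -0.58 and 0.01 on the others. Without array 2 the median was -0.13 (camera adjusted p = 0.00733; adjusted p = 0.853 with an estimated correlation). Over the list alone 10 members then passed, 1 higher and 9 lower, and Msx2, Postn and Sfrp2 passed over all genes, all lower.

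**Figure D4:**
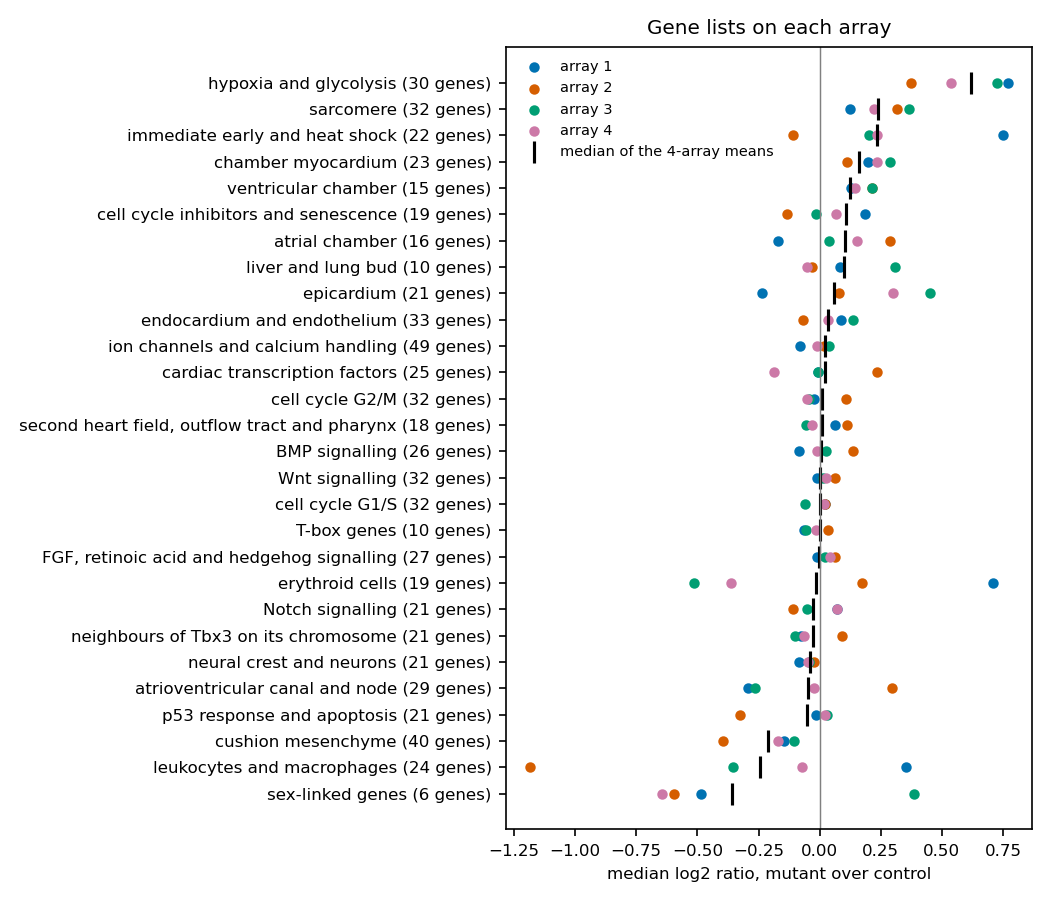
Median log2 ratio of mutant over control (horizontal axis) of each of the 28 gene lists (vertical axis, with the number of genes measured), on arrays 1 to 4 as coloured points and as the median of the 4-array means (black bar). Hypoxia and glycolysis genes lie above 0 on all arrays, and leukocyte genes lie at -1.18 on array 2.

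Among other cell types, the endocardial list (33 genes) had a median of 0.04 (camera adjusted p = 0.214), with Ramp2 at -0.16 ± 0.18, and a median of 0.09 without array 2 (camera adjusted p = 0.0688). In that setting 7 members passed over the list alone, 6 higher and 1 lower. Klf2, at 0.03 ± 1.41, was at 2.08 on array 2 and between -0.96 and -0.21 on the others, with a mean of -0.66 without array 2 (adjusted p = 0.10), and its second probe read -0.54 ± 0.07, lower on all 4 arrays. The epicardial list (21 genes) had a median of 0.06 (camera adjusted p = 0.214), with Krt18 at 0.40 ± 0.59 and Krt8 at 0.33 ± 0.36. Its 1 member past the threshold adjusted over the list alone was the keratin Krt19 at 1.38 ± 0.49, higher on all 4 arrays. Without array 2 the epicardial median was 0.16 (camera adjusted p = 0.173). Of its members 5 then passed over the list alone, 4 higher and 1 lower, and Krt19 and Rarres2, at 0.91, passed over all genes. Erythroid genes (19) had medians of 0.71 and 0.18 on arrays 1 and 2 and of -0.51 and -0.36 on arrays 3 and 4 (camera adjusted p = 0.502), with the embryonic globins Hbb-bh1 at 1.10 ± 0.76 and Hbb-y at 0.84 ± 1.12. Leukocyte genes (24) had a median of -1.18 on array 2 and of 0.35, -0.36 and -0.07 on arrays 1, 3 and 4 (camera adjusted p = 0.137; median 0.07 without array 2, adjusted p = 0.923), with Lyz2 at -0.81 ± 0.82 and Pf4 at 0.53 ± 1.18. The second heart field list (18 genes; Foxc2 at 0.20 ± 0.31 and Foxc1 at -0.28 ± 0.15), the neural crest list (21 genes; Ets1 at 0.01 ± 0.08 and Erbb3 at -0.34 ± 0.10) and the liver and lung bud list (10 genes; Afp at 1.26 ± 1.36 and Trf at -0.23 ± 0.16) had medians of 0.01, -0.04 and 0.10 and camera adjusted p values of 0.834, 0.428 and 0.528. In these 3 lists no member passed, over all genes or over the list alone, on 4 arrays. Without array 2, 4 neural crest members (1 higher, 3 lower) and 2 second heart field members (both lower) passed over the list alone, and the neuronal gene Dcx, at -0.78, passed over all genes (adjusted p = 0.0477). The liver and lung bud list then had none, with a median of 0.25. The 6 sex-linked genes had a median of -0.36 (camera adjusted p = 0.624). Xist was at 0.98 ± 0.73, and the Y-linked Eif2s3y was at 0.57 on array 3 and between -1.02 and -0.65 on the others.

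Immediate early and heat shock genes stood higher, most of all on array 1. The list's 22 genes had a median of 0.23 (camera adjusted p = 0.0262; adjusted p = 0.866 with an estimated correlation), with 0.75 on array 1 and -0.11, 0.20 and 0.23 on arrays 2 to 4. No member passed over all genes or adjusted over the list alone, and the brightest, Hspa8 and Jund, were at 0.41 ± 0.25 and -0.12 ± 0.25. Without array 1 the median was 0.04 (camera adjusted p = 0.339), and without array 2 it was 0.40 (camera adjusted p = 0.00154; adjusted p = 0.853 with an estimated correlation), with 6 members past the threshold over the list alone, all higher. Fosl2, at 0.56 without array 2, passed over all genes in that setting (adjusted p = 0.0421).

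Cell cycle genes were close to 0. The G1/S list (32 genes; Mcm6 at 0.08 ± 0.11 and Mcm4 at 0.05 ± 0.03) had a median of 1.78e-05 and the G2/M list (32 genes; Birc5 at 0.13 ± 0.14 and Mki67 at -0.13 ± 0.44) of 0.01, with camera adjusted p values of 0.730 and 0.788 and no member past either limit. Cell cycle inhibitors and senescence genes (19) had a median of 0.11 (camera adjusted p = 0.603). Among members that passed when adjusted over the list alone, Cdkn1a was higher at 0.32 ± 0.11 and Cdkn2c lower at -0.41 ± 0.22, whereas the brightest members Cdkn1c and Igfbp5 were at 0.30 ± 0.24 and -0.37 ± 0.44. The p53 list (21 genes; Phlda3 at -0.17 ± 0.18 and Perp at -0.26 ± 0.24) had a median of -0.05 (camera adjusted p = 0.583), and Cdkn1a and Trp53inp1, at -0.51 ± 0.22, passed when adjusted over the list alone. Without array 2, 1 G1/S member, Ccne2 at 0.61, passed over all genes. The inhibitor list's median was then 0.20 (camera adjusted p = 0.236), with 4 members past the limit over the list alone. The p53 median was 0.04, with 5 members past that limit, 4 higher and 1 lower.

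No signalling list was shifted on 4 arrays. In the Notch list (21 genes, median -0.03, camera adjusted p = 0.502) the ligand genes Dll1 and Dll4 were at -0.48 ± 0.14 and 0.36 ± 0.19, and these, Heyl at -0.33 ± 0.09, Dtx1 at -0.32 ± 0.15 and Dtx4 at 0.41 ± 0.24 passed when adjusted over the list alone, whereas the brightest members Hey1 and Dlk1 were at 0.04 ± 0.51 and -0.11 ± 0.29. The BMP list (26 genes; Id2 at -0.22 ± 0.48 and Bambi at -0.01 ± 0.26) and the Wnt list (32 genes; Wnt2 at 0.17 ± 0.71 and Fzd1 at -0.15 ± 0.58) had medians of 0.01 and 0.00186 and camera adjusted p values of 0.948 and 0.834, with no member past either limit. Without array 2, 8 BMP members (2 higher, 6 lower) and 5 Wnt members (2 higher, 3 lower) passed over the list alone, and Msx2 of the BMP list passed over all genes. In the list of FGF, retinoic acid and hedgehog genes (27 genes, median -0.00444, camera adjusted p = 0.528; Dusp6 at 0.38 ± 0.35 and Smo at -0.26 ± 0.12), Cyp26b1, which degrades retinoic acid, was at 0.54 ± 0.11 and passed when adjusted over the list alone. Of 25 cardiac transcription factors (median 0.02, camera adjusted p = 0.428; Zfpm1 at -0.18 ± 0.38 and Gata6 at -0.01 ± 0.27), Mef2c at 0.40 ± 0.10 and Srf at 0.34 ± 0.11 passed when adjusted over the list alone. The 21 measured neighbours of Tbx3 on its chromosome had a median of -0.03 (camera adjusted p = 0.834), with Erp29 at 0.30 ± 0.22 and Ptpn11 at 0.08 ± 0.11, and Tmem116 at 0.29 ± 0.05 and Med13l at 0.33 ± 0.16 higher and Rbm19 at -0.26 ± 0.09 and Dtx1 lower when adjusted over the list alone. Without array 2 the members past that limit numbered 7 in the Notch list, 6 in the list of FGF, retinoic acid and hedgehog genes, 5 among the cardiac transcription factors and 7 among the neighbours of Tbx3, with none past the threshold over all genes in these 4 lists. The median of the cardiac transcription factors was then -0.05.

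The genes called without array 2 had ratios on array 2 of the same sign in 121 of 193 cases. Those with the largest means over arrays 1, 3 and 4, chosen after their values were seen, were Kcne3 at 2.84 ± 0.11, Chac1, a glutathione-degrading stress gene, at 2.60 ± 0.26, the endothelial gene Esm1 at 2.19 ± 0.04 and Nppb at 1.92 ± 0.42 (SD, n = 3; adjusted p = 0.00268, 0.0155, 0.00268 and 0.0350). On the lower side Gcgr at -1.17 ± 0.22, Car3 at -1.15 ± 0.18 and Eef1a2 at -1.07 ± 0.16 followed Tbx3 at -1.33 ± 0.11. On array 2 itself Kcne3 was at 0.59, Chac1 at -0.47, Esm1 at -1.20 and Eef1a2 at 0.25.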

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

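The tests of failed hybridisation and of blood content, the settings that remove the running median, the correlations without 206 genes and the genes said to be picked were chosen only after the results were seen. Of 173 results examined for an array far from the other 3, 12 had one, and 9 of these 12 were on array 2. Chance alone picks out about 1 in 20.

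On array 2, far from the other 3 arrays, Gja1 read -2.64 (others 0.39 to 0.68), Esm1 -1.20 (2.15 to 2.23) and Kcne3 0.59 (2.76 to 2.97). Igfbp5 at 0.29 (others -0.66 to -0.54), Id2 at 0.49 (-0.55 to -0.39) and Bmp2 at 0.48 (-0.52 to -0.37) were positive there alone, and Srf was at 0.17 (0.39 to 0.41). The median of the p53 list was -0.32 there, and the SD of all log2 ratios was 0.49. On array 1, Ankrd37 read 1.72 (0.50 to 0.62). On array 3 the median of the G1/S list was -0.061 (0.02 on the others), and the median of the sex-linked genes was 0.39 (-0.64 to -0.49). Spike-in spots, which the comparisons do not use, gave a log10 ratio at a nominal 1 to 1 of 0.00718, 0.134, 0.220 and 0.30 on arrays 1 to 4 in the scanner software's values.

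Array 2 stood apart in its log2 ratios: 206 genes picked for being at least 4-fold lower on array 2 and within 2-fold on the mean of the others had a median log2 level of 11.29 in control pool 2, 8.24 in mutant pool 2 and between 7.49 and 7.75 in the other 6 pools. Without these genes the SD on array 2 went from 0.49 to 0.37. Its rank correlations with arrays 1, 3 and 4 were then 0.13, 0.0060 and -0.02, against 0.13, 9.4e-05 and -0.02 with them. Leaving out 206 of 19089 genes can hardly move a rank correlation. These values therefore cannot tell whether what raised the 206 genes also shifted other genes by less. How array 2 differs over the other genes remains unexplained. A failed labelling or hybridisation is argued against by the spike-in spots of array 2, whose observed and nominal ratios correlated at 0.994 (0.992 to 0.994 on the others). Limb bud in control pool 2 is argued against by a marker median of 0.24 on array 2 (9 genes), with a median level of 7.37 in that pool. Trophoblast markers (7 genes) had a median of 0.11 on array 2 and a median level of 7.54 in that pool. Of these 7, 6 were well above background in the other 3 control pools, so their median cannot decide. On array 2, 1 of the 7 was at least 2-fold lower, Prl3d1 at -1.02, and Tpbpa was at -0.68. The level of Prl3d1 was 9.02 in control pool 2 and between 7.33 and 10.63 in the other control pools. Maternal uterine tissue in control pool 2 stays open. The 14 measured markers of decidua, uterus and uterine natural killer cells were written down before their values were looked at. Their median on array 2 was -0.92, just short of the bound of -1. Klrb1c and Esr1 were at -3.07, whereas Hoxa9, Igfbp4 and Cryab were at 0.17, 0.34 and 0.36. Of these markers 12 were well above background in the other 3 control pools. Uterine tissue need not lower their ratios much, so this median cannot decide. On array 2, 7 of the 14 were at least 2-fold lower and 0 at least 2-fold higher. Among these 7, Gzmg and Klrb1c had log2 levels of 11.27 and 9.55 in control pool 2. In the other control pools their levels lay between 6.07 and 6.60. Spp1, Penk and Sfrp4 were picked after their values were seen. Their log2 levels were 15.97, 17.54 and 14.86 in control pool 2 and between 7.09 and 9.42 in the other control pools. No biological explanation was tested.

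Hypoxia and glycolysis genes stood higher in the mutant pools, with a positive list median on each array. A difference between the dyes that depends on brightness is argued against as the whole cause by the list median with the running median removed, 0.57 against 0.62 before. The list median also lay at percentile 100 of 10000 random lists matched on intensity, past the bound set beforehand. Those lists drew genes independently, whereas this list's estimated correlation was 0.28, so the percentile alone does not decide. More blood in the mutant pools is argued against by a list median of at least 0.54 on the 2 arrays where the erythroid median was below -0.3. Dye effects particular to single probes stay open: 85.7% of 21 other probes for 14 of these genes were positive, against 59.3% of the other probes of all genes, which passes the bound of 85% by less than 1 probe, and no array had the dyes exchanged. The time between collection and lysis, and the genotype itself as a cause, were not tested.

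Sarcomere genes stood higher in the mutant pools, above all those with very bright probes. Their list median lay at percentile 99.4 of 10000 random lists matched on intensity, past the bound set beforehand. Those lists drew genes independently, whereas the list's estimated correlation was 0.28, and the very brightest genes had mostly dimmer genes to match. The percentile therefore cannot decide whether a difference between the dyes that depends on brightness is the whole cause. With the running median removed the list median went from 0.24 to 0.12, so brightness may account for a part, and without array 2 as well it was 0.05 (camera adjusted p = 0.412). More chamber muscle in the mutant pieces and the genotype itself were not tested.

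The 8 sign patterns of the 4 arrays are too few for a share under 0.05. The real pattern called 1 gene, and the highest of the other 7 patterns called 0, so 1 of 8 called as many. Past 2-fold these values were 1 and 0 (1 of 8), and at an adjusted p under 0.1 they were 26 and 0 (1 of 8). For gene lists they were 6 and 7, and 5 of 8 patterns called as many as the real one. The number of list calls therefore does not set the real pattern apart.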

How the results depend on the processing

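The settings that remove the running median, and the estimated correlation without array 2, were chosen after the data were seen. Tbx3 stayed negative in all 20 alternatives and past the threshold in 11, with adjusted p values from 0.000849 to 0.602. It missed the threshold with the processed signals and the series table (-1.34 in both; adjusted p = 0.0547 in both), without background subtraction (-1.35; 0.0538), with all probes (-1.35; 0.0504), with the mean over probes (-0.74; 0.120) and without variance moderation (-1.35; 0.112). Leaving out 1 array gave -1.39 to -1.32. The count of 1 gene changed and the count of 1 past 2-fold became 3 and 3 with the processed signals and with the series table (Cnr1, Rax and X12388, higher), 7772 (7202 of them higher) and 291 with median centring, 402 and 29 with array weights, 191 and 13 with the channels separate and no replicate block, and 70 and 21 with the running median removed and without array 2. Both were 0 by limma without background subtraction, with all probes and with the mean over probes, and 0 without variance moderation, at 2808, 3948, 2538 and 2524 tests with an unadjusted p under 0.05. Leaving out 1 array gave 0 to 193 and 0 to 32. The count of 26 at an adjusted p under 0.1 became 7 with the processed signals and the series table, 10192 with median centring, 1 with all probes, 0 with the mean over probes, 1696 with array weights, 355 with no replicate block, 1 with the running median removed, 1070 with that and without array 2, 1 without variance moderation, and 0 to 1543 with 1 array left out. The 6 list calls became 11 with median centring, 0 with an estimated correlation with or without array 2, 1 with directional fry and 13 with mixed fry, and 6 to 8 with 1 array left out. The form with an estimated correlation has few degrees of freedom here. Without array 2 it gave 0 of 28 lists an unadjusted p under 0.05, so calls lost in that form do not decide against a list. Without the 61 genes that lists share, 25 lists were left and 5 were called; the ventricular list was not among the 25. Of 24 alternatives the hypoxia and glycolysis call was kept in 21, sarcomere in 20, chamber myocardium and cushion mesenchyme in 19, immediate early genes in 17 and the ventricular list in 12 of 23. Median centring moved the median of all genes by 0.23 and took 12 named genes from a negative value to a positive one past the threshold: Fhl2 0.39, Mdk 0.59, Ramp2 0.46, Mki67 0.56, Phlda3 0.35, Jund 0.59, Bambi 0.58, Smo 0.31, Zfpm1 0.51, Gata6 0.57, Gja5 0.33 and Des 0.22. Over the 20 alternatives, 40 of the 138 named genes other than Tbx3 changed sign, 83 times in all. Leaving out array 1, 3 or 4 left fewer arrays, but so did leaving out array 2, where 193 genes passed. The cause of the changes was not tested. Slide and scan date as blocks were not run, since 1 slide and 1 scan held all arrays. Cnr1, Rax and X12388 were at 1.67, 1.45 and 2.56 in the processed signals and at 0.40, 0.33 and 0.32 with normexp, and were well above background in 0 of 4 control channels.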

Other observations

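Some genes that the report leaves out, chosen after their values were seen, passed over all genes when array 2 was left out. They were higher in the mutant AVC: the collagen prolyl hydroxylase gene P4ha2 at 1.01, the growth factor binding protein gene Igfbp3 at 1.07, the endothelin gene Edn1 at 0.87 and the growth factor gene Hbegf at 0.85 (adjusted p = 0.0388, 0.0350, 0.0450 and 0.0334). The lipoprotein receptor gene Vldlr and the hormone gene Stc2 were at 1.41 and 1.69 (adjusted p = 0.0343 and 0.0477). On array 2 Vldlr was at -1.06 and Stc2 at -0.70.

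Some transcripts that were high in control pool 2 were also higher in mutant pool 3 than in control pool 3. On array 3 the decidual prolactin gene Prl8a2 was at 2.86, Spp1 at 1.89, the granzyme gene Gzmc at 1.49 and Hoxa11 at 1.29, against -1.51, -6.44, -4.56 and -4.48 on array 2. The log2 level of Prl8a2 was 11.27 in mutant pool 3, 10.25 in control pool 2 and between 7.35 and 8.89 in the other 6 pools. Others that were high in control pool 2 showed little or no rise on array 3: Klrb1c was at 0.00081, Penk at 0.02, Myh11 at -0.22 and Esr1 at -0.46. The 14 measured markers of decidua, uterus and uterine natural killer cells had a median of 0.05 on array 3. The genes named here were singled out after their values were seen.

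Sex-linked genes differed between the 2 pools of an array. Xist was at 1.54, 0.82, 0.01 and 1.56 on arrays 1 to 4, and the Y-linked Ddx3y at -1.13, -0.81, 0.46 and -0.96. The Y-linked Eif2s3y and Kdm5d were also negative on arrays 1, 2 and 4 and positive on array 3. Ddx3y and Kdm5d were chosen after their values were seen. Whether the mutant and control pools differed in the sex of their embryos, beside genotype, was not tested.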
